A study of Mus musculus with 16 samples.

How the data were processed

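Adult neural stem cells, the dividing precursors of new hippocampal neurons, were isolated from the dentate gyrus of male WT and Fmr1 KO littermates of 8 to 10 weeks and grown with EGF and FGF2 at 20 ng/ml each, per the labels' protocols. Cells were treated with cycloheximide, which stalls elongating ribosomes, at 100 µg/ml for 10 min before harvest. Cytoplasmic RNA was taken from part of each lysate, and the rest was digested with RNase A and RNase T1 and the monosome fraction collected from a sucrose gradient for footprint libraries. The footprint libraries carry unique molecular identifiers of 5 nt in replicates 1 and 2 and of 8 nt in replicates 3 and 4. The RNA libraries were made with an amplification kit (NuGEN Ovation V2), and no identifier is named for them. Per the labels, replicates are independently isolated cells.

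The authors deposited estimated counts per gene, which hold whole numbers, and a table of TPM rounded to whole numbers (treated here as a score, because rounding removed its fraction). The submitters' processing notes name cutadapt 1.7.1, Bowtie2 2.1.0, TopHat2 2.0.9, SAMtools 0.0.19, bedtools 2.22.0, RSEM 1.2.11 and the mouse build mm10, without role or order; how the identifiers were collapsed and whether strand was used are not given in the sources used here. RSEM divides reads that match several genes by expectation, so values of near-identical genes such as histones, ribosomal protein genes with pseudogenes and clustered protocadherins are uncertain. Overlapping and antisense genes cannot be told apart where strand is not used. Cycloheximide treatment before lysis and nuclease digestion shape footprint counts; both genotypes got the same treatment, and whether it acted alike in them was not tested.

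Of 20436 rows, 27 had a bare number in place of a gene symbol, as spreadsheet conversion of symbols to dates leaves behind. They held 0.244% to 0.422% of the counts of a library and were left out of library sizes and tests, leaving 20409 genes. Of these symbols, 19269 matched the RefSeq table for GRCm38.p6, the assembly of mm10, from which coordinates were taken (1-based). No column was without a sample. A table of the authors' own comparisons that the labels mention was not analysed here.

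Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by genotype, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. RNA was fitted with genotype alone over 8 libraries. Footprints were fitted with genotype and identifier length over 8 libraries. TE was fitted as the assay by genotype interaction in one model over all 16 libraries, with genotype, assay and an identifier term for the footprint libraries, on genes kept in both assays. CPM values are scaled by TMM within an assay, fold changes are log2 of KO over WT, and the SE of a fold change is derived from the quasi-likelihood F statistic. The floor for a group at 0 is 3 counts over the group. Counting intervals and this floor cover counting error only, since reads without identifiers are not independent molecules. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and the design of each fit, with adjustment over the lists of a comparison, and with an estimated correlation and fry as alternatives. There were 32 lists, 8 of them of cell type markers, and 30 had at least 3 members tested in each comparison.

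The tests, designs, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Fmr1, Fxr1 and Fxr2, then the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM. For each list that passed camera or had 3 members past the threshold, it names up to 4 members past the threshold or else the 2 most abundant. A result for 1 gene that the rule names is not reported here. Where fewer than 10 genes passed, it names the 10 with the smallest p. Bcas1, Cspg4, Col5a2, Gbp3, Stmn2, Lama4, Naaa, Pcdhb11 and Myl9 fall outside this rule and were chosen after their values were seen.

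The replicate numbers come from the sample titles, which give WT and KO the same numbers 1 to 4. Deviations from the group means correlated between same-numbered WT and KO libraries at r = 0.481 to 0.613 in RNA and 0.379 to 0.54 in footprints. This was over 0.1 in each pair, so the numbers were taken to pair the samples. The best match of a library had its own number in 8 of 8 cases in RNA and 7 of 8 in footprints, where KO 2 was closer to WT 1. Across different numbers r ran from -0.542 to 0.368 in RNA and from -0.456 to 0.453 in footprints. Some of these also exceeded 0.1, within replicates 1 and 2 or within 3 and 4. The limit of 0.1 therefore cannot tell single pairs from that larger structure. The design without the block is the main one, as fixed, and the blocked value is printed where it changes a call. No pair of replicates held identical values: correlations of log2 CPM between replicates of a group ran from 0.815 to 0.936 in RNA and from 0.847 to 0.969 in footprints.

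The tests were run first on simulated counts drawn with the means and library sizes of these libraries, with 200 genes changed. Each gene was drawn independently with its own estimated spread, without the pairing of replicates or shifts shared by the genes of a culture. At 2, 4 and 8-fold, the RNA test over 11097 genes recovered 3.33%, 58.6% and 82.9% of the changed genes with 4 false calls. The footprint test over 11472 genes recovered 41.7%, 91.4% and 94.3% with 9 false calls, and the TE test over 10863 genes 10.0%, 51.4% and 82.9% with 2 false calls. A 2-fold change in RNA or TE would therefore mostly have been missed at this spread and number of replicates. The rates of recovery and of false calls need not hold for the real libraries, which had such pairing and shared shifts.

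Alternatives were RLE size factors, no count filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.5), the replicate block, replicates 1 and 2 or 3 and 4 alone, surrogate variables (sva 3.50.0), each replicate left out, no identifier term or a term for replicates 1 and 2 against 3 and 4, and for TE the culture as a block and TMM within each assay. Chosen after seeing the data were the culture block together with the replicate block, and the list tests without WT replicate 1 and with the replicate block without pair 1.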

Results

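Ribosome profiling and cytoplasmic RNA sequencing were carried out on adult neural stem cells cultured from the dentate gyrus of male FVB/N mice, either wild type (WT) or lacking Fmr1 (KO). Fmr1 encodes FMRP, an RNA-binding protein that associates with ribosomes and whose loss underlies fragile X syndrome. Ribosome profiling counts the mRNA fragments that ribosomes protect from nuclease (footprints, RPF), so that footprints relative to RNA give a measure of translational efficiency (TE). There were 4 libraries for each of the 4 groups: WT footprints, KO footprints, WT RNA and KO RNA. The 16 libraries came from 8 cultures, each of independently isolated cells, and the RNA and footprints of a culture came from one lysate. Total estimated counts per library ran from 5343042 to 6600023 in RNA and from 9430732 to 17220236 in footprints. Between 12489 and 13134 genes had a count in an RNA library, and between 13173 and 13754 in a footprint library. The study's title names the discrimination of mRNAs by FMRP in these cells; the comparisons below ask which RNAs, footprints and translational efficiencies differed between the genotypes.

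The targeted gene was low in the KO libraries of both assays. Fmr1 (X chromosome, 68678536 to 68717963, mm10) had 144 ± 10.2 normalised CPM (counts scaled to the size of the library) in WT footprints and 19.6 ± 6.97 in KO footprints (mean ± SD, n = 4 each), and the 2 ranges did not overlap. Per library, the WT footprint values were 129, 149.8, 149.4 and 148.7 CPM and the KO values 24.1, 27.0, 12.7 and 14.7 CPM. Fmr1 RNA was 53.1 ± 36.3 CPM in WT and 13.4 ± 12.1 CPM in KO, lower in KO in each of the 4 same-numbered pairs. The library WT RNA 2 stood at 106.8 CPM against 27.4 to 40.9 CPM in the other WT libraries, and KO RNA 2, at 30.9 CPM, exceeded WT RNA 4. The footprint difference was a log2 fold change (KO over WT) of -2.93 (SE 0.22, edgeR quasi-likelihood adjusted p = 0.014). With the replicate number as a block the adjusted p was 0.143. It lay between 0.0565 and 0.134 when WT replicate 2, 3 or 4 or KO replicate 1 or 2 was left out, with the log2 fold change between -2.78 and -3.08 over all 8 omissions. The RNA difference, -1.99 (SE 0.67), did not pass (adjusted p = 1.0), and was -2.81 without KO replicate 2 and -1.39 without WT replicate 2. The paralogs Fxr1 and Fxr2, which encode the other members of the FMRP family, had footprint log2 fold changes of 0.06 (SE 0.12) and 0.06 (SE 0.11) and neither passed. Their RNA log2 fold changes were -0.27 (SE 0.42) and 0.07 (SE 0.20), and did not pass either.

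**Figure D1:**
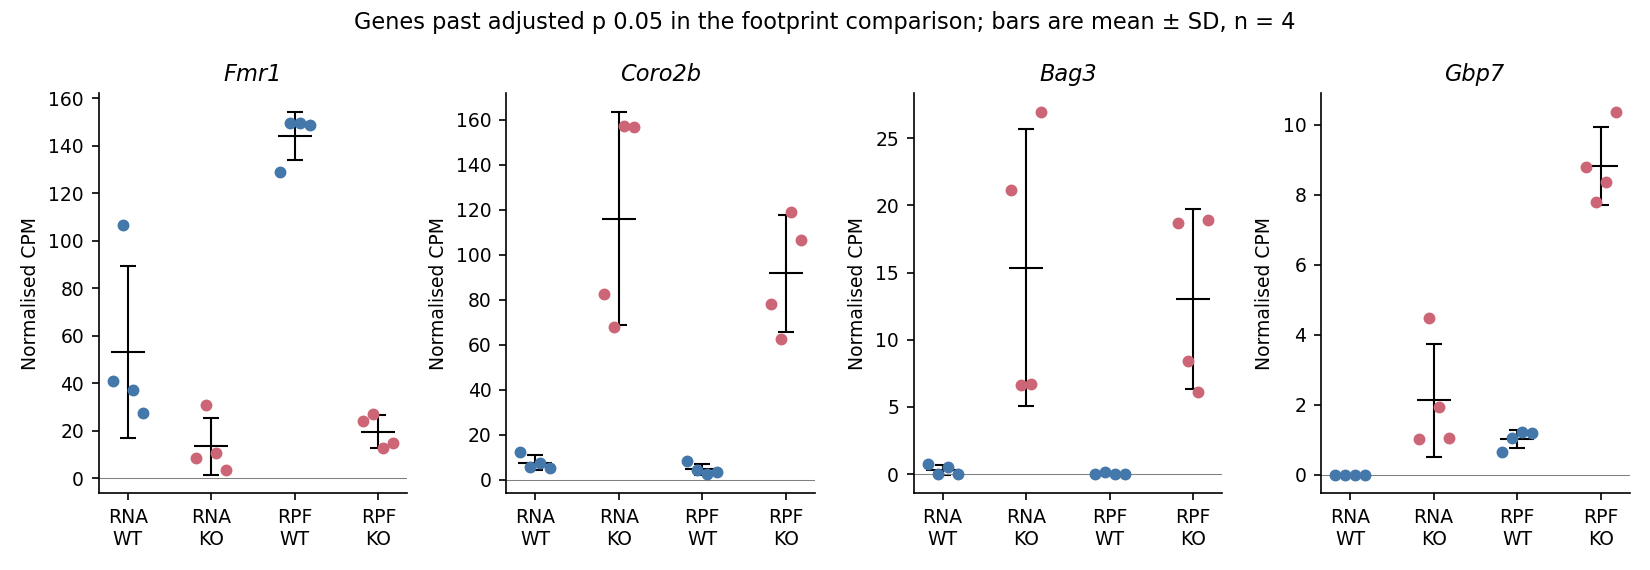
Normalised CPM (y axis, linear) of the 4 genes past adjusted p 0.05 in footprints, by assay and genotype; each point is a library and bars give the mean ± SD of 4 libraries. Fmr1 footprints lie at 129 to 149.8 CPM in WT and 12.7 to 27.0 in KO, while Coro2b, Bag3 and Gbp7 are higher in KO in both assays.

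In cytoplasmic RNA, Coro2b was the gene that separated the genotypes most clearly. Coro2b (chromosome 9, 62419490 to 62537044), a member of the coronin family of actin-binding proteins, had 7.61 ± 3.17 CPM in WT and 116 ± 47.5 CPM in KO RNA (n = 4 each), and was higher in KO in each of 4 pairs. Its log2 fold change of 3.93 (SE 0.41, adjusted p = 0.0427) made it the 1 gene higher among 11097 tested with edgeR's quasi-likelihood test, and 0 genes were lower. Other large differences ran the same way in each of 4 pairs without passing after adjustment. Among those higher in KO, Cyp1b1, a cytochrome P450 enzyme, had 0.631 ± 0.572 CPM in WT and 61.6 ± 55.3 in KO (log2 fold change 6.58, SE 1.03). Bag3, a co-chaperone of HSP70, had 5.58 (SE 0.96), Ndn, the imprinted gene encoding necdin, 5.34 (SE 0.93), and Trf, which encodes transferrin, 3.23 (SE 0.59). Lynx1 had 3.43 (SE 0.69), Eva1c 2.33 (SE 0.41) and Pcdhgb2, a clustered protocadherin, 2.06 (SE 0.44). Among those lower in KO, Nkx2-2, a transcription factor of the oligodendrocyte lineage, had 53.6 ± 11.8 CPM in WT and 5.07 ± 3.98 in KO (log2 fold change -3.40, SE 0.70), and the integrin subunit gene Itga3 had -2.94 (SE 0.52). Their adjusted p-values lay between 0.492 and 0.973.

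Fewer RNA genes stood out at the unadjusted level than chance alone would give. At an unadjusted p under 0.05, 89 genes were higher and 119 lower, 1.87% of those tested, against about 555 expected by chance. The unblocked test was thus conservative, and the low count does not show that few genes changed. DESeq2 with the same design called 13 higher and 7 lower, and limma-voom 0 and 0. With the replicate number as a block, edgeR called 0 genes in either direction (297 higher and 411 lower at an unadjusted p under 0.05). The Coro2b call (adjusted p = 0.0682 with the block) was also lost when any library except KO replicate 2 was left out (adjusted p = 0.0511 to 0.381).

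Several fixed gene lists shifted in RNA when their members were compared with all other genes by camera with a preset inter-gene correlation. Of the 30 lists with at least 3 members tested, 9 passed adjusted p 0.05, 5 upward and 4 downward, although no member of any of them passed by itself. With an estimated correlation 0 of the 30 passed, nor did any by fry (adjusted p = 0.913 for each of the 9). The estimated correlations of the 9 ran from 0.17 for synaptic genes to 0.91 for histones, far above the preset 0.01, so the camera p-values below are too small. As many lists passed in 29 of the 35 ways of splitting the 8 cultures into 4 and 4, the genotypes included. With an estimated correlation, adjusted p = 0.736 for the G2 and mitosis list, 0.831 for the S phase, histone and nuclear pore lists and 0.836 for the proteasome list, the 5 that passed upward. All 28 G2 and mitosis genes had positive fold changes (median log2 fold change 0.37, camera adjusted p = 3.4e-08), with Top2a, a topoisomerase of dividing cells, at 0.54 (SE 0.51) and the mitotic kinase gene Plk1 at 0.30 (SE 0.54). Of the S phase genes, 30 of 32 were positive (median 0.21, adjusted p = 7.1e-05), among them Rrm1, a ribonucleotide reductase subunit, at 0.21 (SE 0.33) and the replication licensing gene Mcm2 at 0.16 (SE 0.50). Replication-dependent histone genes (46 of 59 positive, median 0.10, adjusted p = 7.1e-05) gave Hist1h1d 0.19 (SE 0.56) and Hist1h1e 0.11 (SE 0.41); these near-identical genes share reads and their single values are uncertain. The nuclear pore list (24 of 27 positive, median 0.12, adjusted p = 0.0379) had Nup210 at 0.82 (SE 0.45) and Nup188 at -0.09 (SE 0.25). The proteasome list (28 of 32 positive, median 0.12, adjusted p = 0.0385) had Psmd2 at 0.12 (SE 0.23) and Psmd1 at -0.27 (SE 0.20).

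WT RNA 1 had the lowest level of the 8 RNA libraries in each of these 5 upward lists. The outlier test given below, which judges a gap against the range of the group, set it apart for the G2 and mitosis genes only. In other lists the remaining WT libraries spread as well. S phase genes had a mean log2 CPM of 4.58 in WT RNA 1 and 5.96, 6.64 and 6.81 in WT RNA 2 to 4. Histones rose over WT RNA 1 to 4 (mean log2 CPM 4.44, 5.78, 7.07 and 7.68). The mean log2 CPM of the G2 and mitosis genes was 4.47 in WT RNA 1 against 6.55 to 6.68 in the other WT libraries and 6.45 to 7.18 in KO. Without WT replicate 1 none of the 5 passed, and the medians became -0.08 for S phase, -0.23 for histones, -0.06 for nuclear pore, -0.03 for proteasome and 0.07 for G2 and mitosis genes. The histone, nuclear pore and proteasome lists also did not pass without WT replicate 2 (adjusted p = 0.0868, 0.0635 and 0.43), KO replicate 3 (0.125, 0.204 and 0.45) or KO replicate 4 (0.0763, 0.189 and 0.556). The histone median was -0.13, -0.12 and -0.08 in these omissions. The highest medians came without WT replicate 4, at 0.51 for S phase, 0.61 for G2 and mitosis, 0.61 for histones, 0.30 for nuclear pore and 0.27 for proteasome genes. With both libraries of pair 1 left out and the replicate number as a block, the G2 and mitosis list passed upward with the preset correlation (adjusted p = 0.00396, and adjusted p = 0.779 with an estimated correlation), and the other 4 did not (0.551 to 0.981).

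The 4 lists that passed downward with the preset correlation were extracellular matrix genes, p53 targets, synaptic genes and brain mRNAs bound by FMRP. With an estimated correlation, adjusted p = 0.736 for the first 3 and 0.831 for the FMRP brain targets. Extracellular matrix genes had a median of -0.42 (6 of 28 positive, camera adjusted p = 3.5e-04), with the proteoglycan genes Bcan at -0.27 (SE 0.39) and Ncan at 0.53 (SE 0.40) as its most abundant members. Of the p53 targets, 17 of 18 were negative (median -0.28, adjusted p = 0.00193), including Plk2 at -0.44 (SE 0.34) and Ei24 at -0.04 (SE 0.22). Synaptic genes had a median of -0.23 (11 of 34 positive, adjusted p = 0.00871), with Nrxn2, which encodes a presynaptic neurexin, at -0.22 (SE 0.28). The FMRP brain targets, mRNAs reported to be bound by FMRP in mouse brain and not chosen on these samples, had a median of -0.12 (45 of 134 positive, adjusted p = 0.00871), with Ptprs at -0.31 (SE 0.28) and Prrc2a at 0.13 (SE 0.21). Without WT replicate 1 none of the 4 passed, the medians of the matrix list and the FMRP brain targets turning to 0.06 and 0.02. The matrix list also did not pass without KO replicate 4 (adjusted p = 0.376), the p53 targets without WT replicate 3 (0.498) or KO replicate 4 (0.0845), with a median of -0.04 in the first of these, and the synapse list without WT replicate 2 (0.33) or KO replicate 3 (0.321). The FMRP brain targets did not pass without WT replicate 2 (0.521, median 0.01), KO replicate 3 (0.477) or KO replicate 4 (0.0758). The medians reached -0.52 for the matrix list, -0.39 for the p53 targets and -0.24 for the FMRP brain targets without WT replicate 4, and ran from -0.35 without WT replicate 3 to -0.09 without KO replicate 3 for the synapse list. With the block and without pair 1 the synapse list (adjusted p = 0.00218) and the FMRP brain targets (0.00826) passed downward and the other 2 did not (0.0546 each), while adjusted p = 0.698 for both with an estimated correlation. With the replicate number as a block these 9 lists still passed, and 4 more did, while with an estimated correlation adjusted p was 0.677 to 0.704 for all 13. Cytosolic ribosomal proteins passed upward (adjusted p = 0.00243, against 0.0534 without the block). Downward passed immediate early genes (8.7e-07, against 0.093), oligodendrocyte lineage markers (0.0333, against 0.148) and interferon response genes (0.0329, against 0.0723). The immediate early genes followed the replicate number, with a mean log2 CPM of 8.89 in WT RNA 1, 8.34 in KO RNA 1 and 3.66 to 6.24 in the others, and were lower in KO in all 4 pairs. Without WT replicate 1 but with its partner KO replicate 1 their median was 1.16 (adjusted p = 0.14), while under the block without that pair they were lower (adjusted p = 9.4e-04, and adjusted p = 0.698 with an estimated correlation).

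Among cell type markers, neural stem and progenitor genes were near their WT level in RNA, with 11 of 19 positive and a median of 0.02 (camera adjusted p = 0.57). Markers of neuroblasts and neurons (3 of 14 positive, median -0.35, adjusted p = 0.077), astrocytes (7 of 19 positive, median -0.10, adjusted p = 0.56) and endothelial and mural cells (3 of 4 positive, median 0.76, adjusted p = 0.083) did not pass. Against its median, the astrocyte list went upward by camera, and its mean log2 CPM was higher in KO in 3 of the pairs. With the block and without pair 1 it passed upward (adjusted p = 4.1e-04, and adjusted p = 0.698 with an estimated correlation). Of microglial and ependymal markers, 1 each was expressed enough to be tested. Adjusted over the list alone, Sparcl1 was higher among astrocyte markers, and among oligodendrocyte lineage markers Bcas1 was higher and Nkx2-2 lower; adjusted over all genes tested, none of the 3 passed. Col5a2, a fibrillar collagen gene, was likewise lower among matrix genes and Gbp3 higher among interferon response genes when adjusted over the list alone.

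**Figure D2:**
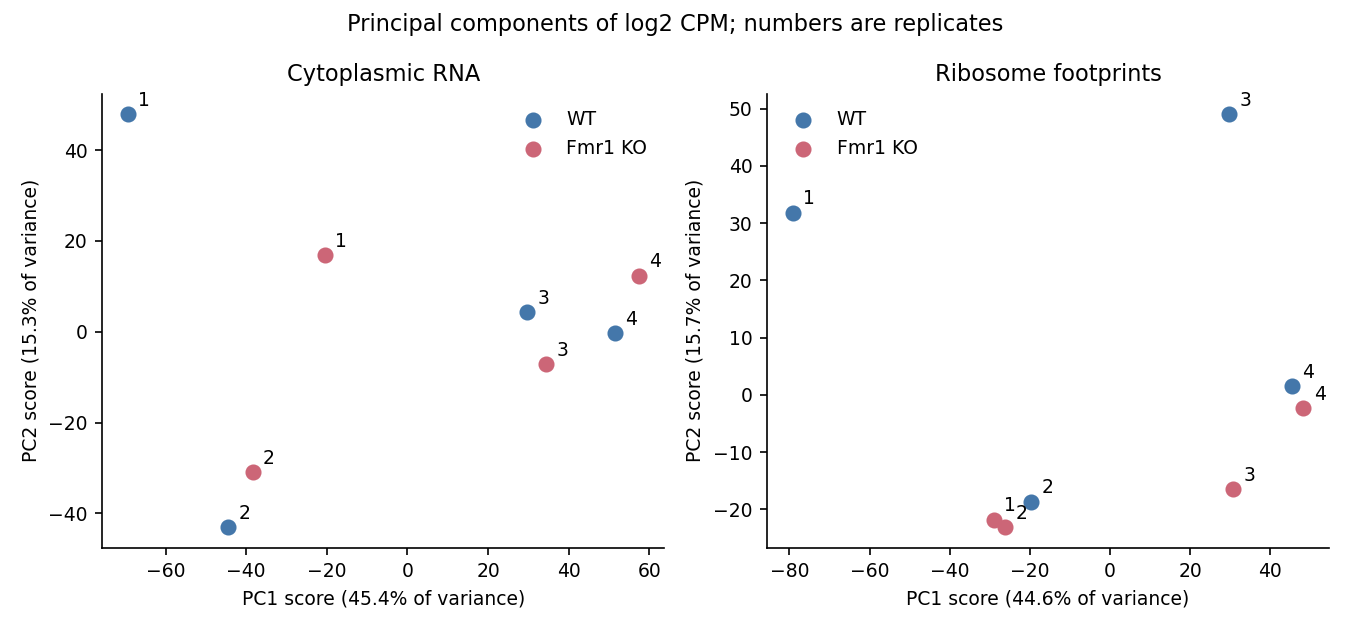
Principal component scores of log2 CPM for the 8 RNA libraries (left) and the 8 footprint libraries (right); colours give the genotype and numbers the replicate. Component 1, with 45.4% of the variance in RNA and 44.6% in footprints, parts replicates 1 and 2 from replicates 3 and 4, and WT replicate 1 lies furthest out at -69.3 and -79.2.

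In ribosome footprints, 3 genes were higher in KO and 1, Fmr1, was lower, of 11472 tested with edgeR's quasi-likelihood test and a term for the length of the molecular identifier. Gbp7 (chromosome 3), an interferon-inducible guanylate-binding protein gene, had 1.03 ± 0.26 CPM in WT and 8.83 ± 1.11 CPM in KO footprints (log2 fold change 3.10, SE 0.26, adjusted p = 0.0147). Its RNA was at 0 counts in all 4 WT libraries and 52 counts over the KO libraries, at least 16.9-fold higher against a floor of 3 counts over the group, and was too low to enter the RNA test. Coro2b footprints were 4.61 ± 2.51 CPM in WT and 91.6 ± 25.8 CPM in KO (log2 fold change 4.31, SE 0.42, adjusted p = 0.0282). Bag3 (chromosome 7) had 2 footprint counts over the 4 WT libraries and 666 over the KO libraries, a ratio of 296 after scaling to library totals (exact 95% interval from counting error 81.6 to 2447, adjusted p = 0.0376). Both WT counts lay in WT RPF 2, so that without it the WT libraries had 0 counts and KO was at least 141-fold higher against a floor of 3 counts over the group. Each of these 3 genes was higher in KO in all 4 pairs. Their calls were lost under the same omissions and block as that of Fmr1, given above, and that of Bag3 also without WT replicate 1 (adjusted p = 0.181). In some settings where Fmr1 and Coro2b kept their calls, the others did not. Bag3 was lost with limma-voom (adjusted p = 0.139). By limma-trend on log2(TPM + 1) and log2(TPM + 0.5), adjusted p was 0.0994 and 0.0568 for Bag3 and 0.21 and 0.263 for Gbp7. In replicates 3 and 4 alone edgeR gave 0.418 and 0.348.

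Below the threshold, the same direction was seen in footprints as in RNA for most of the genes named above. Trf footprints were 61.5 ± 32.3 CPM in WT and 556 ± 355 in KO (log2 fold change 3.22, SE 0.37, adjusted p = 0.0573). Sparcl1, a secreted matricellular protein gene of astrocytes, was at 2.62 (SE 0.39, adjusted p = 0.189). S100a11, a calcium-binding protein gene, had 35.6 ± 14.1 CPM in WT and 6.55 ± 2.88 in KO footprints (-2.44, SE 0.29, adjusted p = 0.0573), and the protocadherin gene Pcdhb4 was at -2.68 (SE 0.34, adjusted p = 0.0808). S100a11 RNA, too low to enter the RNA test, was 1.05 ± 0.238 CPM in WT and 0.791 ± 0.658 in KO, and higher in KO in 2 of the pairs. Gprasp2, which like Fmr1 lies on the X chromosome, had 5.01 (SE 0.66, adjusted p = 0.0953) and Stxbp5l 5.48 (SE 0.80, adjusted p = 0.18), from WT means of 0.184 and 0.105 CPM. At an unadjusted p under 0.05, 236 genes were higher and 291 lower, 4.59% of those tested, against about 574 expected by chance. DESeq2 called 56 higher and 26 lower, and limma-voom 3 and 3. With the replicate number as a block edgeR called 0 genes in either direction, with 303 higher and 360 lower at an unadjusted p under 0.05. Leaving out WT replicate 2, 3 or 4 or KO replicate 1 or 2 also brought the count to 0, and without KO replicate 4 it was 11 higher and 3 lower.

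Footprints of cell division genes were higher in KO by camera with the preset correlation, while adjusted p = 0.887 with an estimated correlation for each of the 8 lists that passed. The estimated correlations of the 8 ran from 0.34 for p53 targets to 0.94 for G2 and mitosis genes. As many lists passed in 32 of 34 splits of the cultures, the genotypes included. In WT RPF 1 the G2 and mitosis genes had a mean log2 CPM of 5.73, against 7.57 to 7.88 in the other WT libraries and 7.85 to 7.87 in the KO libraries. All 28 G2 and mitosis genes (median log2 fold change 0.47, adjusted p = 1.0e-08) and all 32 S phase genes (median 0.33, adjusted p = 1.9e-06) had positive values. Mki67, the gene of the proliferation antigen Ki-67, was at 0.85 (SE 0.37), Top2a at 0.64 (SE 0.37), Rrm1 at 0.40 (SE 0.30) and Pcna, the replication clamp gene, at 0.33 (SE 0.26). Replication-dependent histones (46 of 49 positive, median 0.20, adjusted p = 2.4e-04) and nuclear pore genes (24 of 27, median 0.16, adjusted p = 0.00216) shifted upward as lists, and so did proteasome genes (28 of 32, median 0.10, adjusted p = 0.019) and cytosolic ribosomal protein genes (75 of 78, median 0.09, adjusted p = 0.00738). Examples were Hist1h1b at 0.29 (SE 0.43), Hist1h1d at 0.18 (SE 0.35), Nup210 at 0.89 (SE 0.28), Tpr at -0.22 (SE 0.19), Psmd1 at -0.17 (SE 0.16), Psmb1 at 0.01 (SE 0.14), Rpl4 at 0.17 (SE 0.20) and Rpl19 at 0.05 (SE 0.21). Astrocyte markers passed with a median of 0.13 (13 of 20 positive, adjusted p = 0.0429), led by Sparcl1, the 1 member past the threshold adjusted over the list alone, while Glul was at -0.28 (SE 0.41). Apoe was at 1.08 (SE 0.77) with the identifier term and -0.38 without it. The p53 targets shifted downward (3 of 18 positive, median -0.29, adjusted p = 2.4e-04), with Cdkn1a, which encodes the cell cycle inhibitor p21, at -0.50 (SE 0.25) and Plk2 at -0.46 (SE 0.32).

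No member of these 8 RPF lists passed by itself over all genes tested. Without WT replicate 1 the G2 and mitosis list still passed (median 0.13, adjusted p = 5.5e-04), and so did the astrocyte markers (median 0.34, adjusted p = 4.5e-07). The S phase (adjusted p = 0.918), nuclear pore (0.918), proteasome (0.345) and p53 (0.0807) lists then did not pass, while histones (median -0.13, adjusted p = 0.00788) and cytosolic ribosomal proteins (median -0.11, adjusted p = 2.3e-07) passed in the opposite direction. With both libraries of pair 1 left out and the replicate number as a block, histones did not pass (adjusted p = 0.085). Cytosolic ribosomal proteins (1.1e-05) and p53 targets (0.0307) then passed downward and the G2 and mitosis list (0.00646) and astrocyte markers (7.7e-08) upward. With an estimated correlation, adjusted p = 0.685 for astrocyte markers and 0.851 for the others. Outside the 8 lists, cholesterol synthesis (2.1e-07) and nuclear-encoded oxidative phosphorylation (3.3e-05) then passed downward and synaptic genes upward (0.00798), also with 0.851 at an estimated correlation. The highest medians of the 6 upward lists other than astrocyte markers came without WT replicate 2, from 0.18 for proteasome genes to 0.79 for G2 and mitosis genes, and the p53 median ran from -0.39 without WT replicate 4 to -0.14 without WT replicate 3. Without KO replicate 2, cytosolic ribosomal proteins (adjusted p = 0.331), histones (0.104), nuclear pore (0.104) and proteasome genes (0.286) did not pass. Cytosolic ribosomal proteins also did not pass without KO replicate 1 (0.0531), nor did the p53 targets without WT replicate 3 (0.296) or KO replicate 4 (0.0895). The astrocyte markers did not pass without WT replicate 2 (0.473), 3 (0.121) or 4 (0.165) or KO replicate 2 (0.117), 3 (0.382) or 4 (0.0692). The astrocyte call was lost with the replicate number as a block over all pairs (adjusted p = 0.0912), though not under the block without pair 1, as given above. The median of the astrocyte markers was -0.05 without the term for identifier length (adjusted p = 0.152). Immediate early genes passed downward under the block (adjusted p = 0.0125, against 0.365, and adjusted p = 0.913 with an estimated correlation), but not under the block without pair 1 (0.292). Their mean log2 CPM in footprints was higher in KO in 2 of the pairs.

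**Figure D3:**
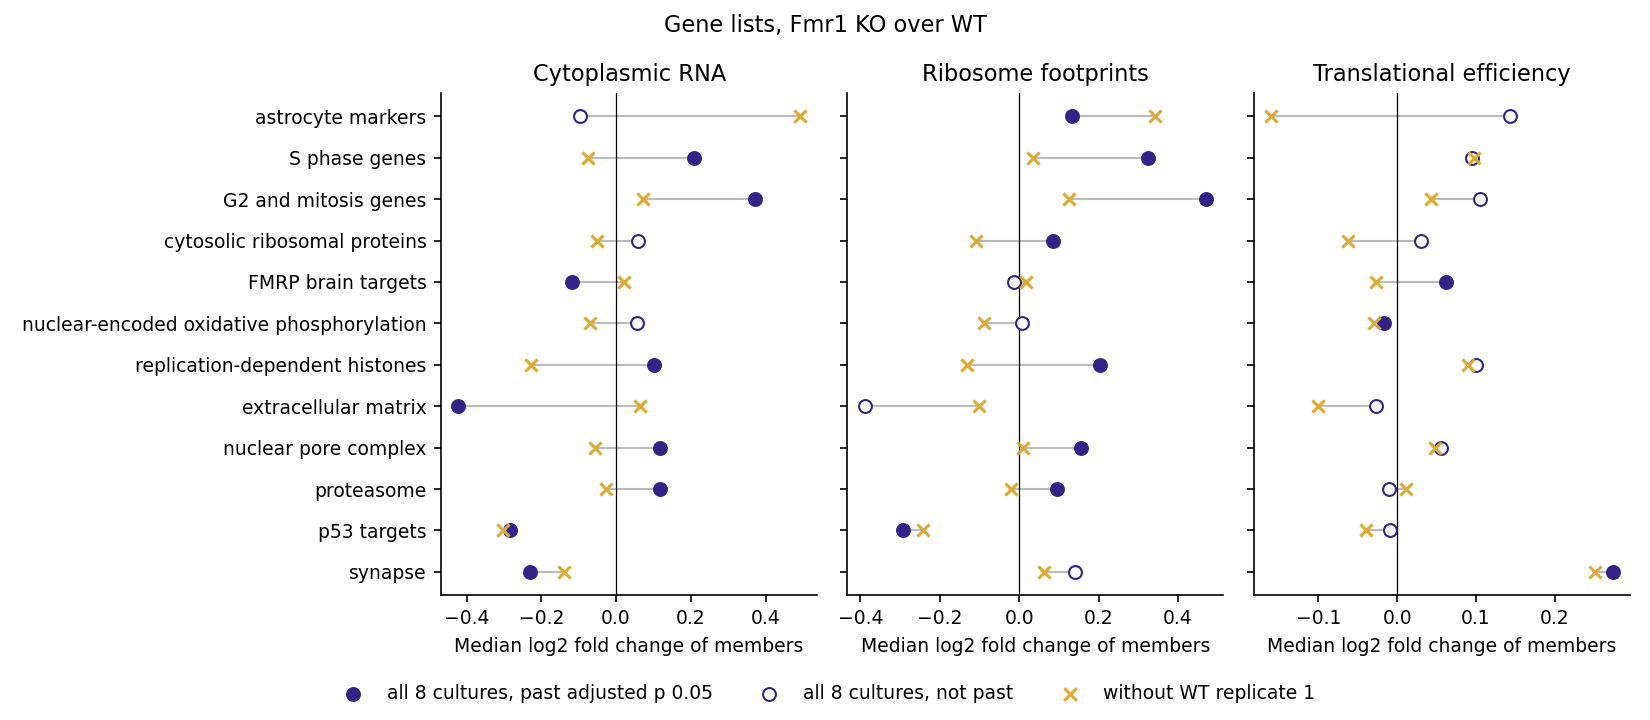
Median log2 fold change (KO over WT, x axis) of the 12 gene lists past adjusted p 0.05 in at least 1 comparison; filled circles passed camera with the preset correlation, open circles did not, and crosses give the median without WT replicate 1. The S phase and histone RNA medians move from 0.21 and 0.10 to -0.08 and -0.23, and the synapse median in translational efficiency from 0.27 to 0.25 (0.20 to 0.49 over all 8 omissions).

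Fold changes of footprints followed those of RNA across genes. Over the 10863 genes in both tests the Pearson correlation of the log2 fold changes was 0.795 (Spearman 0.701) and the slope 0.73, and 76.8% had the same sign; genes are not independent replicates, and both assays sampled the same cultures. The correlation was 0.648 without KO replicate 2 and 0.351 with no count filter. Of the genes called, 1, Coro2b, passed in RNA and footprints in the same direction (15 genes with DESeq2), 0 passed in TE and footprints and 0 in TE and RNA with footprints unchanged.

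**Figure D4:**
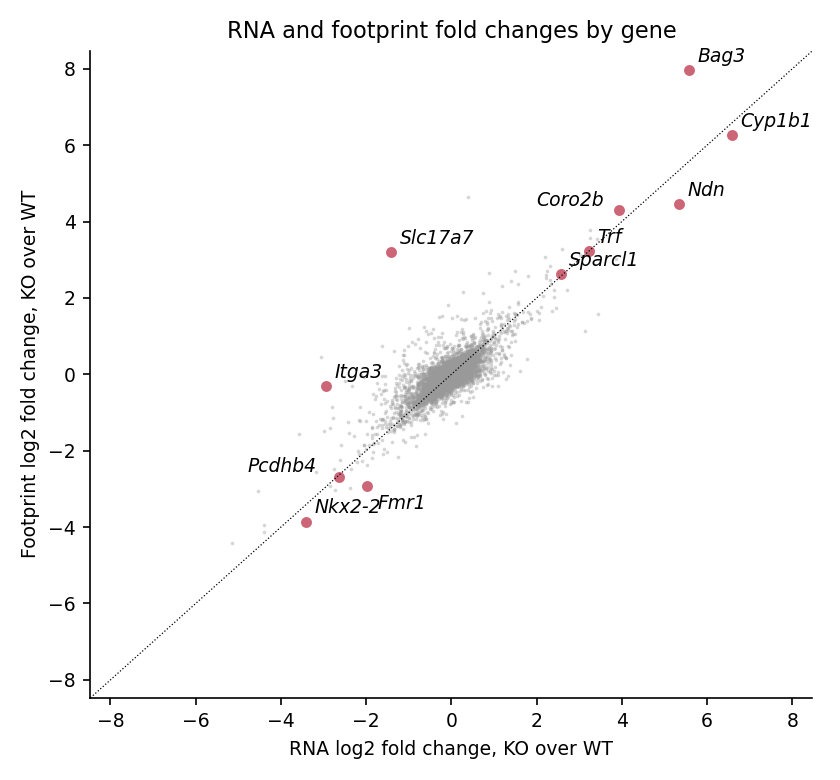
Log2 fold change of footprints (y axis) against RNA (x axis), KO over WT, for the 10863 genes in both tests; each grey point is a gene, named genes are in red and the dotted line marks equal change. Most named genes lie near the line, with Slc17a7 at -1.41 in RNA and 3.20 in footprints and Itga3 at -2.94 and -0.32 as exceptions.

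No single gene passed in translational efficiency. Of 10863 genes tested with edgeR's quasi-likelihood test of the assay by genotype interaction, 0 were higher and 0 lower. At an unadjusted p under 0.05, 7 were higher and 7 lower, where chance alone would give about 543. The test was thus conservative, and the lack of calls does not show that no gene changed. Blocked models also called 0, with 33 higher and 24 lower at an unadjusted p under 0.05 for the replicate number, 80 and 72 for the culture, whose RNA and footprints came from one lysate, and 242 and 178 for both. DESeq2, limma-voom and limma-trend on log2 TPM also called 0. Fmr1 had a TE log2 fold change of -0.93 (SE 0.74), from -1.59 without WT replicate 2 to -0.25 without KO replicate 2. Fxr1 had 0.34 (SE 0.47) and Fxr2 0.00 (SE 0.23). The genes with the smallest p-values were of low abundance and none passed (adjusted p = 1.0). They included Slc17a7, the vesicular glutamate transporter gene, at 4.54 (SE 1.30), the protocadherin gene Pcdhga12 at 4.21 (SE 1.43), Itga3 at 2.65 (SE 0.76), 2010300C02Rik at 1.64 (SE 0.45) and Syp, which encodes the synaptic vesicle protein synaptophysin, at 1.18 (SE 0.49). Toward lower efficiency they included Tmem218 at -1.53 (SE 0.58), Zfp112 at -1.37 (SE 0.49), Fam221a at -1.33 (SE 0.56), Nmi at -1.11 (SE 0.44) and Smim19 at -1.03 (SE 0.43).

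As a list, synaptic genes had higher TE in KO relative to other genes. Of 33 members 28 had positive TE log2 fold changes (median 0.27, camera adjusted p = 6.6e-09), beside an RNA median of -0.23 and a footprint median of 0.14. With an estimated correlation (0.21 for this list), adjusted p = 0.727. The mean log2 CPM of synaptic genes in footprints was 3.38, 3.63, 4.11 and 4.35 in KO 1 to 4 and 3.51, 4.05, 2.82 and 3.68 in WT 1 to 4. Footprints were thus higher in KO in replicates 3 and 4 only, while RNA was lower in KO in all 4. Neuroblast and neuron markers were also higher in the footprints of KO 3 and 4 (4.39 and 4.42) than of KO 1 and 2 (3.52 and 3.58) or of the WT libraries (3.55 to 4.26). In RNA of the same cultures these markers were not raised, at 4.68 and 5.16 in KO 3 and 4 (14 members, against 25 in footprints). KO RNA 1 and 2 had 5.16 and 5.40, and the WT libraries 4.71 to 5.89. Nrxn2 was at -0.03 (SE 0.40), and the synapse list passed with each of the 8 cultures left out in turn (highest adjusted p = 0.00251). Its median moved in these omissions, from 0.20 without KO replicate 3 to 0.47 without KO replicate 1 and 0.49 without KO replicate 2, and was 0.44 without WT replicate 4. FMRP brain targets also shifted upward (88 of 132 positive, median 0.06, adjusted p = 0.00298), with Ptprs at -0.09 (SE 0.35) and Scd2 at -0.15 (SE 0.28) as their most abundant members. Nuclear-encoded oxidative phosphorylation genes shifted downward (30 of 71 positive, median -0.02, adjusted p = 0.0211), with the ATP synthase genes Atp5b at 0.01 (SE 0.36) and Atp5a1 at 0.04 (SE 0.33). With an estimated correlation, adjusted p = 0.996 for both. The FMRP brain targets did not pass without WT replicate 1 (adjusted p = 0.304), WT replicate 2 (0.15), KO replicate 3 (0.962) or KO replicate 4 (0.62), with medians from -0.03 without KO replicate 3 to 0.20 without KO replicate 1. The oxidative phosphorylation genes passed upward without WT replicate 2 (median 0.12, adjusted p = 0.00373) and did not pass without WT replicate 1 (0.181), KO replicate 3 (0.352) or KO replicate 4 (0.876), and their median was -0.17 without WT replicate 4. With the replicate number as a block these 3 lists passed and immediate early genes passed upward (median 0.24, adjusted p = 0.00656, against a median of 0.13 and 0.646 without the block). Under the block without pair 1 the call for immediate early genes was lost (adjusted p = 0.0805). Under the block over all pairs, adjusted p = 0.993 for each of these 4 lists with an estimated correlation. Under the block without pair 1, synaptic genes (adjusted p = 1.6e-13), FMRP brain targets (8.6e-07) and axon guidance genes (0.0109) passed upward. Cytosolic ribosomal proteins (7.0e-10) and oxidative phosphorylation genes (0.00607) then passed downward. With an estimated correlation, adjusted p was 0.794 for the first 3 and 0.917 and 0.991 for the last 2. The main model does not pair the RNA and footprints of a culture. With the culture as a block, camera with the preset correlation passed synaptic genes (adjusted p = 7.4e-10) and FMRP brain targets (5.9e-05) upward. Immediate early genes (8.7e-04) also passed upward and oxidative phosphorylation genes (0.00288) downward. An estimated correlation was not run with the culture block.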

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

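The tests of WT replicate 1 and pair 1, of the splits for the G2 and mitosis list and of each culture left out for the synapse list were chosen after the result was seen. Of 284 groups of 4 libraries tested for a library far from the others, 18 (6.34%) had one, where chance gives about 1 in 20; the groups were named genes and gene lists in each genotype and assay, and values below are normalised CPM.

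Fmr1 was at 106.8 in WT RNA 2, with the other WT RNA libraries at 27.4 to 40.9, and at 129 in WT RPF 1, with the others at 148.7 to 149.8. WT RNA 1 was high for the proteoglycan gene Bcan at 4881 (others 1537 to 1854) and for Apoe, which encodes apolipoprotein E, at 3513 (others 13.6 to 502). WT RPF 1 was low for Rrm1 at 203 (others 516 to 580) and for Atp5b at 1859 (others 2856 to 2905). In KO footprints, Plk1 was at 194 in replicate 1 (others 243 to 248) and Plk2 at 390.0 in replicate 3 (others 231 to 249). Tpr, a nuclear pore gene, was at 387 in KO RNA 2 (others 43.7 to 64.2). Nmi was high in replicate 3 of both genotypes in footprints, at 17.05 in WT (others 11.03 to 11.5) and 16.5 in KO (others 10.8 to 11.7), and Fam221a was at 2.23 in KO RPF 3 (others 1.69 to 1.76). Near the detection limit, Bag3 was at 0.152 in WT RPF 2 (others 0), Ndn at 3.76 in WT RNA 4 (others 0 to 0.615), and Gprasp2 at 1.08 in WT RNA 2 (others 0) and 7.49 in KO RNA 3 (others 0.508 to 1.16).

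The G2 and mitosis genes had a mean log2 CPM of 4.47 in WT RNA 1 (others 6.55 to 6.68) and of 5.73 in WT RPF 1 (others 7.57 to 7.88), so that this culture may account for the cell cycle, histone, nuclear pore and proteasome lists being higher in KO. Without WT replicate 1, 0 of the 5 RNA lists and, leaving the G2 and mitosis list aside, 0 of the 4 footprint lists stayed past the threshold and higher in KO, although the histone, nuclear pore and proteasome lists were also lost without WT replicate 2, KO replicate 3 or KO replicate 4 in RNA and without KO replicate 2 in footprints, so that their loss was not particular to this culture. The G2 and mitosis list in footprints stayed past it with the preset correlation (adjusted p = 0.000551; with an estimated correlation, adjusted p = 0.887 with all cultures), but its median went from 0.47 to 0.13 and the WT levels of 7.57 to 7.88 then spanned those in KO (7.85 to 7.87), so that whether this culture accounts for the whole of it stays open. With pair 1 left out and the replicate number as a block it passed in RNA and footprints (adjusted p = 0.00396 and 0.00646, and adjusted p = 0.779 and 0.851 with an estimated correlation), but 8 of the 34 splits of the footprint libraries gave this list a p as small (-log10 p of 9.46 for the genotypes, up to 17.1 for another split), and chance was not excluded. A difference between the genotypes in the rate of division remains open and was not measured otherwise.

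In 3 lists the RNA and footprint effects differed by the interaction test with the preset correlation (adjusted p = 0.727 for the synapse list and 0.996 for the other 2 with an estimated correlation): the median TE log2 fold change was 0.27 for the synapse list, 0.062 for the FMRP brain targets and -0.017 for nuclear-encoded oxidative phosphorylation. For the 30 of 33 synapse members with a length, 0% of 10000 random lists matched on length and mean expression over both assays had a median as high. RNA abundance by itself was not matched, and genes drawn singly lack the correlation within the list (0.21). Length or abundance was thus not excluded as its cause. The 24 members with a mean count of at least 50 in both assays had a median of 0.23, so that members near the detection limit were not the whole of it, although the other 9 had a median of 1.2. With a culture left out the highest adjusted p was 0.00251 with the preset correlation, but the range of KO levels overlapped that of WT in each omission, and 1 culture was not excluded. Chance was not excluded either, since 3 of the 34 splits gave a p as small (-log10 p of 9.66 for the genotypes, up to 12.1 for another), all of them among the 8 that part all 4 pairs. Footprints of the list were higher in KO in only 2 of the 4 pairs, replicates 3 and 4. Footprints of neuroblast and neuron markers were also high there (4.39 and 4.42 in KO, against 3.52 and 3.58 in KO 1 and 2 and 3.55 to 4.26 in WT). Their RNA was not, at 4.68 and 5.16 in KO 3 and 4 against 4.71 to 5.89 in WT. A difference between cultures or between their footprint libraries, which was not tested, thus stays as open as a change in translation without FMRP.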

How the results depend on the processing

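Beside the alternatives listed before the data were examined, the culture and replicate block together, the replicate block without pair 1 and the tests of lists without WT replicate 1 were chosen after the result was seen. The log2 fold change of Fmr1 footprints stayed between -2.44 and -3.45 in every alternative run, and its adjusted p passed 0.05 in all but the replicate block, replicates 1 and 2 alone and 5 of the 8 omissions. The synapse list in TE and the G2 and mitosis list in footprints passed under each camera setting run with the preset correlation, but with an estimated correlation neither did (adjusted p = 0.727 and adjusted p = 0.887). Over the named genes and lists, 1559 values kept their direction and their side of the threshold, 124 kept the direction and lost the call, 31 kept it and gained a call and 106 changed sign or test direction. Most named genes had no call in the main fit to lose. The 1559 thus mostly counts values that stayed short of the threshold and is no measure of how firm the calls were. Among counts, classes and the correlation, 164 values stayed within the limits set and 83 did not. The replicate block ended the gene calls and changed the list calls given with the results, and no other call. Depth and spread limit small changes: in simulated data 2-fold changes were mostly missed in RNA and TE. Apart from fewer genes or libraries where these were left out, the cause was not tested.

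With DESeq2 the counts of genes were 13 higher in RNA, 7 lower in RNA, 56 higher in footprints and 26 lower in footprints. In RNA and footprints alike, 15 genes passed. Sign changes in log2 fold change were Psmb1 -0.0049 in footprints. They also included Fxr2 -0.016 and Atp5b -0.0067 in TE. With limma-voom the counts of genes were 0 higher in RNA and 3 lower in footprints. In RNA and footprints alike, 0 genes passed. Of opposite sign in log2 fold change were Atp5b -0.031 and Atp5a1 -0.0021 in TE. On log2(TPM + 1) the counts of genes were 2 higher in RNA and 1 higher in footprints. In log2 fold change the sign differed for Atp5b -0.0036 in TE. On log2(TPM + 0.5) the counts of genes were 1 higher in footprints. The log2 fold changes of opposite sign were Atp5b -0.0036 in TE. With RLE size factors the counts of genes were 2 lower in footprints. Sign changes in log2 fold change were Psmb1 -0.0050 in footprints. They also included Fxr2 -0.016 and Atp5b -0.0067 in TE. With no count filter the counts of genes were 2 lower in footprints. The RNA and footprint correlation was 0.351. At a mean count of at least 50 the counts of genes were 2 lower in footprints. With the replicate number as a block the counts of genes were 0 higher in RNA, 0 higher in footprints and 0 lower in footprints. In RNA and footprints alike, 0 genes passed. Of opposite sign in log2 fold change were Atp5b -0.033 and Atp5a1 -0.0026 in TE. With the culture as a block the log2 fold changes of opposite sign were Atp5b -0.033 and Atp5a1 -0.0029 in TE. With culture and replicate block together the log2 fold changes of opposite sign were Atp5b -0.033 and Atp5a1 -0.0028 in TE. With surrogate variables the counts of genes were 0 higher in RNA and 2 lower in footprints. In RNA and footprints alike, 0 genes passed. Sign changes in log2 fold change were Rpl19 -0.036 and Psmb1 -0.019 in footprints. With a term for replicates 1 and 2 against 3 and 4 in RNA the counts of genes were 0 higher in RNA. The lists past the threshold numbered 14 in RNA. Without the identifier term the log2 fold changes of opposite sign were Apoe -0.38, Rpl19 -0.00084 and astrocyte markers -0.053 in footprints. They also included Atp5b -0.0029 in TE. In replicates 1 and 2 alone the counts of genes were 0 higher in RNA, 0 higher in footprints and 0 lower in footprints. In RNA and footprints alike, 0 genes passed. In log2 fold change the sign differed for Ei24 0.070 in RNA. They also included Apoe -0.46 in footprints as well as Atp5b -0.10 in TE. In replicates 3 and 4 alone the counts of genes were 0 higher in RNA and 1 higher in footprints. In RNA and footprints alike, 0 genes passed. The log2 fold changes of opposite sign were Rrm1 -0.040, Mcm2 -0.11, Plk1 -0.054, Hist1h1d -0.038, Hist1h1e -0.11, Bcan 0.22 and Nrxn2 0.15 in RNA. They also included Fxr1 -0.029, Glul 0.17, Rrm1 -0.0078, Rpl4 -0.11, Rpl19 -0.14, Hist1h1b -0.12, Hist1h1d -0.030 and Psmb1 -0.037 in footprints as well as Fxr2 -0.015, Atp5a1 -0.017 and Nrxn2 0.026 in TE. With the replicate block and without pair 1 the lists past the threshold numbered 5 in TE. With an estimated correlation the lists past the threshold numbered 0 in RNA, 0 in footprints and 0 in TE. With fry the lists past the threshold numbered 0 in RNA, 0 in footprints and 0 in TE.

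With each culture left out in turn, the ranges were 0 to 1 for genes higher in RNA, 0 to 11 for genes higher in footprints, 0 to 3 for genes lower in footprints and 0 for genes passing in RNA and footprints alike. They were 0.648 to 0.805 for the correlation of RNA and footprint fold changes, 1 to 18 for lists past the threshold in RNA, 3 to 16 for lists past the threshold in footprints and 3 to 11 for lists past the threshold in TE. Gene log2 fold changes that changed sign or test direction in RNA ran from -0.68 to 0.13 for Fxr1, -0.0073 to 0.18 for Fxr2, -0.057 to 0.38 for Rrm1 and -0.14 to 0.61 for Mcm2. In RNA also, the range was -0.032 to 0.74 for Plk1, -0.13 to 0.61 for Hist1h1d, -0.11 to 0.44 for Hist1h1e and -0.46 to 0.29 for Bcan. In RNA further, the range was -0.24 to 0.067 for Nup188, -0.024 to 0.29 for Psmd2 and -0.18 to 0.045 for Ei24. Gene log2 fold changes that changed sign or test direction in footprints ran from -0.015 to 0.10 for Fxr1, -0.55 to 0.12 for Glul, -0.0053 to 0.31 for Rpl4 and -0.13 to 0.21 for Rpl19. In footprints also, the range was -0.076 to 0.68 for Hist1h1b, -0.11 to 0.54 for Hist1h1d and -0.092 to 0.10 for Psmb1. Gene log2 fold changes that changed sign or test direction in TE ran from -0.089 to 0.066 for Fxr2, -0.23 to 0.12 for Ptprs, -0.23 to 0.21 for Atp5b and -0.14 to 0.19 for Atp5a1. In TE also, the range was -0.10 to 0.10 for Nrxn2. List medians that changed sign or test direction in RNA ran from -0.076 to 0.51 for S phase genes, -0.24 to 0.022 for FMRP brain targets, -0.23 to 0.61 for replication-dependent histones and -0.52 to 0.063 for extracellular matrix. In RNA also, the range was -0.056 to 0.30 for nuclear pore complex and -0.027 to 0.27 for proteasome. List medians that changed sign or test direction in footprints ran from -0.011 to 0.34 for astrocyte markers, -0.11 to 0.24 for cytosolic ribosomal proteins, -0.13 to 0.58 for replication-dependent histones and -0.021 to 0.18 for proteasome. List medians that changed sign or test direction in TE ran from -0.032 to 0.20 for FMRP brain targets and -0.17 to 0.12 for nuclear-encoded oxidative phosphorylation.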

Other observations

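The tests of the X chromosome and of oligodendrocyte lineage markers were chosen after the result was seen. In both assays 13 genes differed at least 4-fold between the genotypes with no overlap of their 4 and 4 libraries, 8 of them higher in KO and 5 lower. By chance 2.86% of genes would show no overlap in 1 assay, and the assays share their cultures. Higher in KO were Trf, Naaa, Coro2b, Ndn, Sparcl1, Bcas1, Cyp1b1 and Bag3, with RNA log2 fold changes from 2.41 for Bcas1 to 6.58 for Cyp1b1. Lower were the oligodendrocyte lineage factor Nkx2-2, the clustered protocadherins Pcdhb4 and Pcdhb11, the fibrillar collagen gene Col5a2 at -4.54 in RNA and -3.05 in footprints, and the myosin light chain gene Myl9 at -3.19 and -2.56. Adjusted over the list alone, members past the threshold in footprints were Nkx2-2, Bcas1, Sparcl1, Cspg4 (-0.69), Stmn2 (2.94), Lama4 (4.36) and Gbp3 (1.37, and 1.66 in RNA). None of these passed over all genes tested by edgeR's quasi-likelihood test.

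A segment of the X chromosome carried along with the Fmr1 mutation is a possible explanation for such separated genes. As 0 of the 13 lay on the X chromosome, they did not lie in such a segment. An effect of the segment on genes elsewhere was not tested and stays open. Within 10 Mb of Fmr1, 0 of 59 genes had an unadjusted p under 0.05 in RNA against 1.88% elsewhere, and 1 of 58 in footprints against 4.60% (Fisher's exact test, p = 0.63 and 0.523). So few genes at such low shares cannot decide whether that window differs. More oligodendrocyte lineage cells in KO might raise Trf and Bcas1, yet the median RNA log2 fold change of 9 such markers was -0.57, with 2 of 9 positive. That list has 22 members, so most were not tested, and it includes Bcas1 and Nkx2-2 from the 13 genes. The median is thus not independent of these genes and covers only the markers tested. Chance was not excluded at 0.05: 2 of the 35 splits gave as many such genes, the genotypes with 13 and the split of replicates 1 and 2 from 3 and 4 with 79, which points to that structure of the samples, while the highest of all other splits was 9. Other differences between the independently isolated cultures remain open.

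Other splits of the libraries were fitted in the same way as the genotypes. In RNA, 2 of 35 splits called as many genes as the real one: the genotypes with 1 and the split of replicates 1 and 2 from 3 and 4 with 3007, while the highest of the others was 0; with the replicate number as a block the real count was 0. In footprints only 1 of 34 splits, the real one, called as many as 4 genes, a share under 0.05, and the highest other called 1. This does not exclude chance, since the replicate numbers were taken to pair the samples and most splits do not part all 4 pairs. Fmr1, the targeted gene, was 1 of the 4, and with the replicate number as a block the count was 0. Among the 8 splits that part all 4 pairs only the real one called as many, and 8 splits are too few for a share under 0.05. For TE, 34 of 34 splits called as many as the real 0, and the highest other was 0. As many lists passed in 29 of 35 splits in RNA (9 for the genotypes, highest other 21), in 32 of 34 in footprints (8, highest other 20) and in 25 of 34 in TE (3, highest other 18), so that chance was not excluded for any of these counts of lists. The correlation of RNA and footprint fold changes was as high in 3 of 34 splits (0.795 for the genotypes, highest other 0.825). Among the 8 splits that part all 4 pairs, the highest others were 0 genes in RNA, footprints and TE, 16, 19 and 6 lists, and a correlation of 0.825.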
